A study of Homo sapiens with 12 samples.

How the data were processed

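Expression was measured on 12 oligonucleotide arrays of Affymetrix (type Human Genome U133 Plus 2.0), which read most human transcripts with short probes grouped into probe sets. Per the labels, each array holds biotin-labelled RNA of 1 primary fibroblast culture. For each of 6 breast carcinoma specimens, called cases 1, 2, 5, 6, 7 and 8 after the numbers in the sample titles, 1 culture came from the carcinoma (carcinoma-associated fibroblasts, CAF) and 1 from adjacent normal breast tissue (normal fibroblasts, NF). Per the labels' protocols, the cells were grown in DMEM with 10% fetal bovine serum and harvested at confluence, in an early passage, once no epithelial cells were left. Parallel cultures were stained for pan-cytokeratin, von Willebrand factor and vimentin to judge purity, and for alpha smooth muscle actin and S100A4. RNA was isolated with a column kit for small samples and amplified with a kit that incorporates biotin.

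The authors deposited the array values as intensity on a linear scale, 1 value per probe set and array, made with RMA per the submitters' processing notes. RMA corrects background, quantile-normalizes the arrays and summarises the probes of a set. Its version and annotation release are not given in the sources used here. A deposited series table and a deposited workbook both hold these intensities, and 0 values differed between them. The workbook also holds the authors' own comparison per probe set. Per the file headers and the series' design text, the authors gave a posterior probability of equivalent expression of CAF and NF from an empirical Bayes model. A deposited q-value stands beside it, whose test is not given in the sources used here. The authors' fold column equalled the ratio of the arithmetic mean CAF to the mean NF intensity, checked on the values. Their deposited p-value of an F test equalled that of a comparison of the CAF and NF variances of log values, and a deposited ratio beside it equalled the ratio of the variances of linear values. How the deposited q-value of that test was made is not given in the sources used here. Each table column was assigned to a sample by the labels, and 0 columns of array values had no sample.

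All tests were made here on log2 intensities. Of 54675 probe sets, 62 control probe sets and then the 40% with the lowest mean over the 12 arrays were left out, so that 32768 were tested. The lowest kept probe set had a geometric mean intensity of 33.1. CAF and NF were compared with limma 3.58.1 in R 4.3.3, with a linear model per probe set, the case as a block and moderated variances. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the 32768 probe sets, and an adjusted p under 0.05 was called. Values are given as the difference CAF minus NF on the log2 scale with its standard error (SE) over 6 pairs, or as the fold of geometric means. RMA values of dim probe sets are compressed towards the background, so their folds are understated.

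Fixed gene lists, 31 in all, were tested with limma's camera in the same design, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists. Of these, 22 cover pathways and gene families and 9 cover cell type markers and the stained proteins. Each gene was represented by its brightest kept probe set. Members past the threshold were counted over all probe sets and adjusted over the list alone. Camera with an estimated correlation, fry, and exact sign flips of the mean list score over the 6 cases were run beside it. A donor effect was tested with limma's moderated F test of the case terms. Spread was compared per probe set by limma on absolute deviations from the group median. Distances between arrays were root mean square log2 differences. Distances, the likeness of paired arrays and the likeness of the CAF minus NF profiles were tested by exact permutation. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

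Designs, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule named the 12 genes per direction with the largest fold among probe sets past the threshold that changed one way in all 6 cases, filled up by smallest p where fewer passed. It also named up to 4 members of each list by smallest p, the genes of the stained proteins, 5 genes per direction of the spread test and the 8 genes with the largest donor F outside sex-linked, HLA and common deletion genes. Of the genes under this rule, 2, of which 1 passed the threshold, are not reported here by name and are kept in all counts. Genes outside this rule are said to be chosen after their values were seen. The alternatives covered the pairing, the filter, the variance prior, array weights, normalization, the probe set per gene, an empirical Bayes mixture model, the threshold, the set test and each case left out in turn.

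The design text states that CAF and NF are pairs from the same specimens, and the titles carry the case numbers, so the case is a block in the model. The deviations of CAF and NF from their group means correlated with a mean of 0.406 within a case, from 0.276 to 0.602 for single cases, and with a mean of -0.081 between cases. The difference of 0.487 was the largest of all 720 pairings (exact permutation, one-sided p = 0.00139, the smallest possible). Of the 12 arrays, 11 had the array of their own case as the closest of the other group.

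Gene symbols came from the deposited workbook and were updated with a table of RefSeq symbols for assembly GRCh38.p14. Of 19862 symbols in the workbook, 18298 matched a current symbol after 4098 had been updated. With 1 symbol stood 47572 probe sets, with several 0, with none 6973, and 68 held a symbol that spreadsheet software had turned into a date and were left unnamed. The kept probe sets stand for 15252 genes. Probe sets of related genes can share transcripts, which applies to probe sets used here for MYH11, AKR1C1, AKR1C2, KRT8, KRT18, TPSAB1, IGF2, ADAM10 and CD163, among others. The workbook's gene name column gives neurotrimin for HNT.

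The procedure was tested on simulated data with the real probe sets and spreads. Of 67 probe sets changed by 1 on the log2 scale, 82.1% were recovered, of 67 changed by 2, 97.0%, and of 66 changed by 3, 98.5%, with 3 false among 188 calls. These shares hold for the simulated changes and do not give the share of real differences found. In the real arrays, 218 probe sets had a shared direction in all cases and a mean difference of at least 2-fold. Only 9 probe sets that differed at least 2-fold passed the threshold there. The donor test recovered 168 of the 200 strongest simulated donor effects, a share that does not carry over to weaker ones. Camera called 0 of 31 lists when nothing was changed and genes were drawn independently. In the real arrays genes move together, and there the 31 other assignments of CAF and NF within cases gave 3 to 15 called lists, so this 0 does not show that list calls are free of chance ones. The spread test recovered 0 of 200 probe sets given 8 times the CAF spread past the adjusted threshold and 150 at an unadjusted p under 0.05, so 0 calls from it leave open whether spreads differ. The number of arrays limits the precision of every value. Median intensities ran from 48.9 to 51.5 over the arrays and single values from 5.04 to 27592.7.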

Results

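Paired cultures of carcinoma-associated fibroblasts (CAF) and normal breast fibroblasts (NF) from 6 cases were profiled on 12 arrays, 6 of each kind. CAF are the fibroblasts that surround carcinoma cells in a tumour, and NF are those of the breast tissue beside it. The design asked which genes differ between CAF and NF of the same case and how heterogeneous both kinds of culture are. After the filter on dim probe sets, 32768 probe sets of 15252 genes were compared. Values are differences CAF minus NF in log2 intensity with SE over 6 pairs unless stated otherwise.

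Of the named genes, 8 were higher in CAF than in NF past the threshold. TNFSF4, which encodes the costimulatory OX40 ligand, rose by 2.36 on the log2 scale (SE 0.18, n = 6 pairs, 5.12-fold). RASGRF2, an exchange factor for Ras and Rac, rose by 2.26 (SE 0.17, 4.79-fold). The neuronal adhesion protein gene HNT rose by 1.72 (SE 0.16, 3.30-fold), and SUGCT, which encodes a mitochondrial CoA transferase, by 1.37 (SE 0.12, 2.58-fold). The growth factor gene PDGFC was already bright in NF and rose by 0.98 (SE 0.10, 1.98-fold). GSAP, DYSF, which encodes the membrane repair protein dysferlin, and TFPI, an inhibitor of coagulation, rose by 1.15, 1.14 and 0.81, with SE of 0.11, 0.12 and 0.09. Adjusted p from limma ran from 0.0236 for RASGRF2 and TNFSF4 to 0.0464 for DYSF and TFPI, and each gene was higher in CAF in 6 of 6 cases.

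Lower in CAF past the threshold were 4 genes, each in 6 of 6 cases, of which 3 are given here. FAM110B had a difference of -1.33 (SE 0.12, 2.51-fold higher in NF, adjusted p = 0.0326) and is among the dim genes, with a mean log2 intensity of 4.57 in CAF. DKFZP586K1520, named only by its clone, had -1.31 (SE 0.14, adjusted p = 0.0464). CEMIP, which takes part in the breakdown of hyaluronan, had -0.67 (SE 0.07, adjusted p = 0.0449).

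In all, 13 probe sets of 12 genes passed, 9 higher and 4 lower in CAF. RASGRF2 passed with 2 probe sets, the other at 1.10 (adjusted p = 0.0326). Of the 13, 9 differed at least 2-fold, 7 higher and 2 lower. At an unadjusted p under 0.05 stood 5025 probe sets, 2294 higher and 2731 lower, against 1638 expected without any difference. The direction was shared by all 6 cases in 3060 probe sets, or 9.34% against 3.125% expected by chance, and 218 of these had a mean difference of at least 2-fold, 130 higher and 88 lower.

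The genes next in order missed the threshold, although each pointed the same way in 6 of 6 cases. On the side of CAF were CCN4, a secreted matricellular protein of the Wnt pathway, at 1.61 (SE 0.18, adjusted p = 0.0521), LZTS1 at 1.45 (SE 0.16, adjusted p = 0.0521), and PARD6G at 0.55 (SE 0.07, adjusted p = 0.0603). On the side of NF, ALDH1A1, an enzyme of retinoic acid synthesis, had the widest difference at -2.60 (SE 0.33, 6.06-fold higher in NF). TWIST2, a mesenchymal transcription factor, stood at -1.25 (SE 0.15), PLPP3, a lipid phosphatase, at -1.15 (SE 0.14), PRR15 at -0.99 (SE 0.12), and EGFR, the epidermal growth factor receptor, at -0.78 (SE 0.10). ABHD17C, GAS1 and CYP11A1 stood at -0.74, -0.73 and -0.69. These 8 genes had an adjusted p of 0.0603. Other probe sets of some genes showed little or none of the difference, with 0.05 for HNT, -0.02 for LZTS1, -0.02 for GAS1 and 0.12 for EGFR. For PARD6G the others stood at 0.02, -0.02 and -0.06. Of the genes past the threshold, TFPI had other probe sets at 0.20, 0.41 and 0.57, CEMIP at -0.34 and PDGFC at 0.44 and 1.18. Those of GSAP (0.99) and FAM110B (-0.96 and -0.89) kept more of the difference. All of these other probe sets missed the threshold. Further probe sets went the same way as the named one, with 1.75 for HNT, 0.77 for LZTS1, -0.62 for GAS1 and -0.75 for EGFR.

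**Figure D1:**
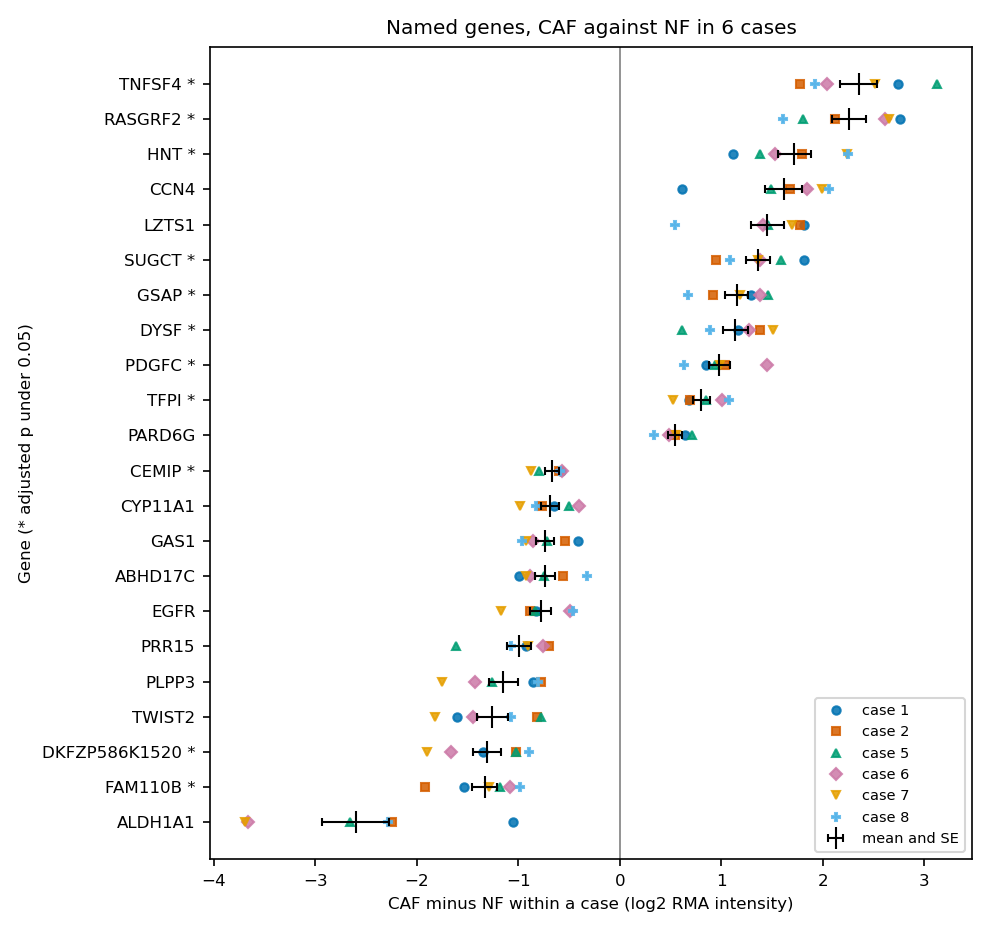
Difference CAF minus NF in log2 RMA intensity (horizontal axis) for the 22 genes of this comparison that are named above (vertical axis), with a point per case, and the mean with its SE in black. The points of every gene lie on one side of 0, and asterisks mark the 11 of them past the threshold, from TNFSF4 at 2.36 to FAM110B at -1.33.

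The number of calls depended on single cases. Without case 2, 6 or 7, limma called 0 probe sets, with 3795, 3684 and 3643 at an unadjusted p under 0.05, and without case 5 it called 6, whereas 49 passed without case 1 and 32 without case 8. Without the case as a block, 5 probe sets passed, all higher in CAF, of which 4 were among the 13. Markers of other cells differed between cultures of some cases, as described with the cell type lists, and the count was 24 without cases 1 and 2, with 3 of the 13 among them, and 0 without cases 2 and 5 (3374 at an unadjusted p under 0.05). With each case left out, without the block, without the filter and with centred arrays, the 12 genes were past the threshold in 50 of 108 values. RASGRF2 lay between 2.16 and 2.39 there and CEMIP between -0.69 and -0.62, where leaving out a case could not turn a direction shared by all 6.

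The authors' deposited table holds 98 probe sets with a posterior probability of equivalent expression under 0.05, 60 higher and 38 lower in CAF. At least 2-fold apart in the authors' deposited table were 61 of them, 40 higher and 21 lower, from 43 genes. In the authors' deposited table the lowest q was 0.312, so 0 probe sets had a q under 0.05. Of the 98 probe sets of the authors' deposited table, 94 were kept here, all 94 had an unadjusted limma p under 0.05, 87 had 1 direction in all 6 cases, and 7 were among the 13 called here. The 98 and the 13 rest on unlike measures, a posterior probability and an adjusted p of the blocked fit after the filter. An unpaired empirical Bayes mixture fitted here without the filter gave 107 probe sets with a posterior under 0.05, and 92 of them were among the 98. Chosen after their values were seen, the largest folds among these 98 in the authors' deposited table were those of ST6GALNAC5, a sialyltransferase, at 12.2 and 6.45 for its 2 probe sets, and of the sodium and calcium exchanger SLC24A3 at 6.31.

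Contractile and matrix genes were then compared as fixed lists, most of whose members are bright in both cultures. Of 18 contractile genes, which carry the myofibroblast phenotype, 10 rose and 0 fell when adjusted over the list alone, and 0 passed over all probe sets. ACTG2, the enteric smooth muscle actin, rose by 2.56 (SE 0.65, 5 of 6 cases), MYLK by 0.42 (SE 0.12), TNS1 by 0.35 (SE 0.10) and MYL9 by 0.41 (SE 0.12). The list as a whole averaged 0.44 and was higher in CAF in 6 of 6 cases (camera, adjusted p = 7.46e-07, and adjusted p = 0.786 with an estimated correlation). Pericyte and smooth muscle markers, of which 3 are in other lists, averaged 0.52 in 6 of 6 cases, and 7 of 16 rose and 2 fell when adjusted over the list alone, against 0 over all probe sets. MYH11, a smooth muscle myosin, rose by 2.13 (SE 0.40), the pericyte proteoglycan CSPG4 by 1.02 (SE 0.20) and the receptor NOTCH3 by 0.83 (SE 0.16), while the potassium channel subunit ABCC9, a pericyte marker, fell by 0.77 (SE 0.12). Camera gave that list an adjusted p of 0.0492, with an adjusted p = 0.786 with an estimated correlation, and the call ended without case 1, 6 or 7 (0.155, 0.0753 and 0.108) and with arrays centred on their median (0.0866).

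Among 23 collagen chains, 7 rose and 0 fell when adjusted over the list alone, and 0 passed over all probe sets. COL10A1, a collagen of hypertrophic cartilage, rose by 2.73 (SE 0.48, 6.64-fold), COL11A1, a fibrillar chain, by 1.83 (SE 0.35, 3.57-fold), COL8A2 by 1.21 (SE 0.26) and COL7A1, the anchoring fibril collagen, by 0.57 (SE 0.09), each in 6 of 6 cases. The sizes were uneven, since COL10A1 differed by only 0.24 in case 2 against 4.10 in case 5. COL11A1 differed by only 0.18 in case 5 against 3.18 in case 6. The whole list missed the threshold with a mean of 0.39, a median of 0.07 and 6 of 6 cases higher (camera, adjusted p = 0.0503), and it passed without case 2 (0.0256), case 5 (0.00351) or case 6 (0.0252), without the block (0.0297) and without the filter (0.0478). Enzymes of collagen maturation rose, with 11 of 17 higher and 2 lower when adjusted over the list alone and 0 over all probe sets. The crosslinking oxidases LOXL3 and LOXL2 rose by 0.99 (SE 0.17) and 0.39 (SE 0.11) and the lysyl hydroxylase PLOD1 by 0.32 (SE 0.08), while PCOLCE2, which aids procollagen cleavage, fell by 0.73 (SE 0.20). The list averaged 0.21 in 5 of 6 cases (camera, adjusted p = 0.00291, and adjusted p = 0.786 with an estimated correlation).

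Glycoproteins and proteoglycans of the matrix went the other way. Of 30 measured, 6 fell and 2 rose when adjusted over the list alone, and 0 passed over all probe sets. The elastic fibre gene FBLN1 fell by 1.72 (SE 0.36, 3.30-fold higher in NF), the small proteoglycan OGN by 1.56 (SE 0.28, 2.94-fold higher in NF) and PODN by 0.60 (SE 0.13), while MFAP2, a microfibril protein, rose by 1.53 (SE 0.26). The list averaged -0.33 and was lower in CAF in 6 of 6 cases (camera, adjusted p = 0.00683, and adjusted p = 0.792 with an estimated correlation), a call that ended without case 5 (-0.24, adjusted p = 0.103). Matrix proteases and their inhibitors averaged 0.08 with 3 of 6 cases higher (camera, adjusted p = 0.869) and 0 of 26 passed over the list alone or over all probe sets. The aggrecanase ADAMTS5 stood at -1.40 (SE 0.32), ADAM19 at 0.70 (SE 0.19), the urokinase receptor PLAUR at 0.71 (SE 0.21) and PLAT at -0.58 (SE 0.18). Integrins and adhesion molecules averaged 0.30 in 6 of 6 cases (camera, adjusted p = 0.00952, and adjusted p = 0.792 with an estimated correlation), although CADM1 alone of 26 rose when adjusted over the list alone, by 2.53 (SE 0.53), and 0 over all probe sets. ITGA11, a collagen receptor chain, stood at 0.58 (SE 0.16), ITGA3 at 0.90 (SE 0.26) and PCDH18 at -0.62 (SE 0.16), and the list missed the threshold without case 2 (adjusted p = 0.0511).

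Of 20 markers often reported for CAF, 14 of which are also in other lists, COL11A1 alone rose when adjusted over the list alone and 0 over all probe sets. ITGA11 and MMP11, a stromelysin, stood at 0.58 (SE 0.16) and 0.68 (SE 0.24), and the list averaged 0.11 in 4 of 6 cases (camera, adjusted p = 0.647). The stained proteins gave little separation. The mesenchymal VIM differed by -0.02 (SE 0.06), S100A4 by -0.01 (SE 0.26) and the endothelial VWF by 0.02 (SE 0.08). ACTA2, alpha smooth muscle actin, stood at 0.80 (SE 0.25, 5 of 6 cases, adjusted p = 0.212), at 15289.5 ± 1927 intensity units in CAF and 9974 ± 5151 in NF (SD, n = 6). The keratins KRT7, KRT8, KRT18 and KRT19 stood at -0.54, -0.13, -0.32 and 0.35, and the basal keratins KRT5 and KRT14 at 1.32 (SE 0.80) and 1.08 (SE 1.11). Of these 10 genes 0 passed by either adjustment, and the list averaged 0.26 with 4 of 6 cases higher (camera, adjusted p = 0.787). That sign rested on case 2, with -0.05 without it, 0.47 without case 8 and -0.22 without cases 1 and 2. In case 2, KRT14, KRT5 and KRT19 differed by 6.26, 5.08 and 4.07, while KRT18 stood at 0.14. KRT14 differed by 3.59 in case 1 and by -2.04 and -2.74 in cases 5 and 8.

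Signalling genes moved in both directions. Of 40 growth factors, 9 rose and 9 fell when adjusted over the list alone, and PDGFC alone passed over all probe sets. TGFB2, HBEGF, a ligand of the EGF receptor, and PDGFA rose by 2.21 (SE 0.29), 1.31 (SE 0.22) and 1.10 (SE 0.19), and the list averaged 0.09 in 3 of 6 cases (camera, adjusted p = 0.430). Targets of transforming growth factor beta averaged 0.25 in 4 of 6 cases, and 7 of 25 rose and 2 fell when adjusted over the list alone against 0 over all probe sets, with 13 members shared with other lists. INHBA, an activin chain, rose by 0.89 (SE 0.23) and BHLHE40 by 0.67 (SE 0.19), while elastin, ELN, fell by 0.49 (SE 0.13). This list missed the threshold (camera, adjusted p = 0.0678) and passed without case 5 (0.00785) or case 8 (0.0127).

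Of 16 genes of the insulin-like growth factor axis, IGFBP2 rose by 2.60 (SE 0.60, 5 of 6 cases) and the growth factors IGF1 and IGF2 and the receptor substrate IRS2 fell by 1.74 (SE 0.51), 1.12 (SE 0.34) and 0.57 (SE 0.13) when adjusted over the list alone, with 0 over all probe sets. That list averaged -0.12 with 3 of 6 cases higher (camera, adjusted p = 0.175) and passed only without case 6 (0.0252). In the Wnt pathway, 3 of 30 rose and 0 fell when adjusted over the list alone, namely CCN4, the secreted DKK3 at 0.83 (SE 0.18) and the transcription factor LEF1 at 1.05 (SE 0.26), and 0 passed over all probe sets. FZD1, a Wnt receptor, stood at -0.52 (SE 0.15), and the mean of the list was -0.09 with 3 of 6 cases higher (camera, adjusted p = 0.599).

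Inflammatory cytokines and NF-kappaB targets averaged 0.07 in 4 of 6 cases (camera, adjusted p = 0.671), with 3 of 35 higher and 3 lower when adjusted over the list alone and 0 over all probe sets. The eotaxin CCL26 and the cytokine LIF rose by 1.02 (SE 0.16) and 0.96 (SE 0.21), while the interleukin 1 receptor IL1R1 fell by 1.12 (SE 0.17) and TNFAIP2 by 0.57 (SE 0.13). Interferon-stimulated genes averaged -0.10 with 2 of 6 cases higher (camera, adjusted p = 0.618). When adjusted over the list alone, 3 of 31 fell and 3 rose, and 0 passed over all probe sets. The antiviral genes IFIT2 and IFIT1 fell by 1.28 (SE 0.18) and 0.88 (SE 0.12), and the exonuclease ISG20 and the ISG15 protease USP18 rose by 0.37 (SE 0.07) and 0.30 (SE 0.07). Immediate early genes averaged -0.08 with 2 of 6 cases higher (camera, adjusted p = 0.189), and 5 of 30 fell and 1 rose when adjusted over the list alone, against 0 over all probe sets. KLF4, ZFP36, which destabilises mRNA, and MYC fell by 1.12 (SE 0.23), 0.64 (SE 0.09) and 0.50 (SE 0.09), and EGR2 rose by 0.72 (SE 0.15). The immediate early list passed without case 5 (0.0126) or case 6 (0.00791).

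Metabolic lists had small mean differences. Antioxidant genes were lower in CAF in 6 of 6 cases with a mean of -0.24 (camera, adjusted p = 0.00658, and adjusted p = 0.786 with an estimated correlation), and 4 of 29 fell when adjusted over the list alone against 0 over all probe sets. The aldo-keto reductases AKR1C1 and AKR1C2, whose probe sets can read each other, fell by 1.38 (SE 0.25) and 1.38 (SE 0.26), HMOX1, which breaks down heme, by 0.71 (SE 0.13) and TXNRD1 by 0.28 (SE 0.08). The steroid hormone list, which shares 3 genes with other lists, averaged -0.29, lower in 5 of 6 cases (camera, adjusted p = 0.0371, and adjusted p = 0.786 with an estimated correlation). Only AKR1C1 and AKR1C2 of its 17 genes fell when adjusted over the list alone and 0 over all probe sets, with AKR1C3 at -1.20 (SE 0.39) and the estrogen hydroxylase CYP1B1 at -0.51 (SE 0.15), and the call ended without case 2 (0.0854) or case 7 (0.104) and with the mean of all probe sets of a gene (0.0621).

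Hypoxia and glycolysis genes averaged 0.19 in 4 of 6 cases (camera, adjusted p = 0.00281, and adjusted p = 0.792 with an estimated correlation). Without case 6 the mean was 0.12. Of 33 genes, 6 were higher and 3 lower when adjusted over the list alone, and 0 passed over all probe sets. The glucose transporter SLC2A1, the enolase ENO2 and the lactate exporter SLC16A3 rose by 0.97 (SE 0.20), 0.87 (SE 0.19) and 0.71 (SE 0.19), while the peptide hormone ADM, induced by hypoxia, fell by 0.81 (SE 0.16). Sterol synthesis genes averaged 0.12 in 5 of 6 cases (camera, adjusted p = 0.00658, and adjusted p = 0.786 with an estimated correlation). SC5D and EBP rose by 0.79 (SE 0.17) and 0.47 (SE 0.10) as the only 2 of 28 to pass over the list alone, with 0 over all probe sets, and the call of the list ended without the case as a block (0.228) and without case 6 (0.0760).

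Cell cycle genes had no common direction. Of 44, 0 passed by either adjustment, and the mean of 0.06 lay far inside the spread between cases (SD 0.82, 3 of 6 cases higher, camera adjusted p = 0.671). Differences of this list ran from -1.19 in case 1 to 0.83 in case 2, so that it was called higher without case 1 (0.31, adjusted p = 0.000787) and lower without cases 2 and 5 (-0.29, adjusted p = 0.00278). MCM7, CDC6 and CDC45, which act in DNA replication, stood at -0.30, 0.23 and 0.36, and E2F1 stood at 0.10. Of 24 p53 targets 0 passed by either adjustment, with XPC at -0.36 and TP53INP1 at -0.29, and the mean of -0.01, the median of 0.03 and the test, which pointed down, differed in sign (camera, adjusted p = 0.922, 3 of 6 cases higher). Positional genes of the HOX and related families, of which 0 of 35 passed by either adjustment, had a mean of -0.03, a median of 0.05 and a test pointing down (camera, adjusted p = 0.869, 2 of 6 cases higher), with HOXC4 at -0.50 (SE 0.10) and HOXD3 at -0.44 (SE 0.11). Among 26 genes of the unfolded protein response, the chaperone DNAJC3 alone rose when adjusted over the list alone, by 0.53 (SE 0.11), and 0 over all probe sets, with a list mean of -0.01 (camera, adjusted p = 0.970, 3 of 6 cases higher).

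**Figure D2:**
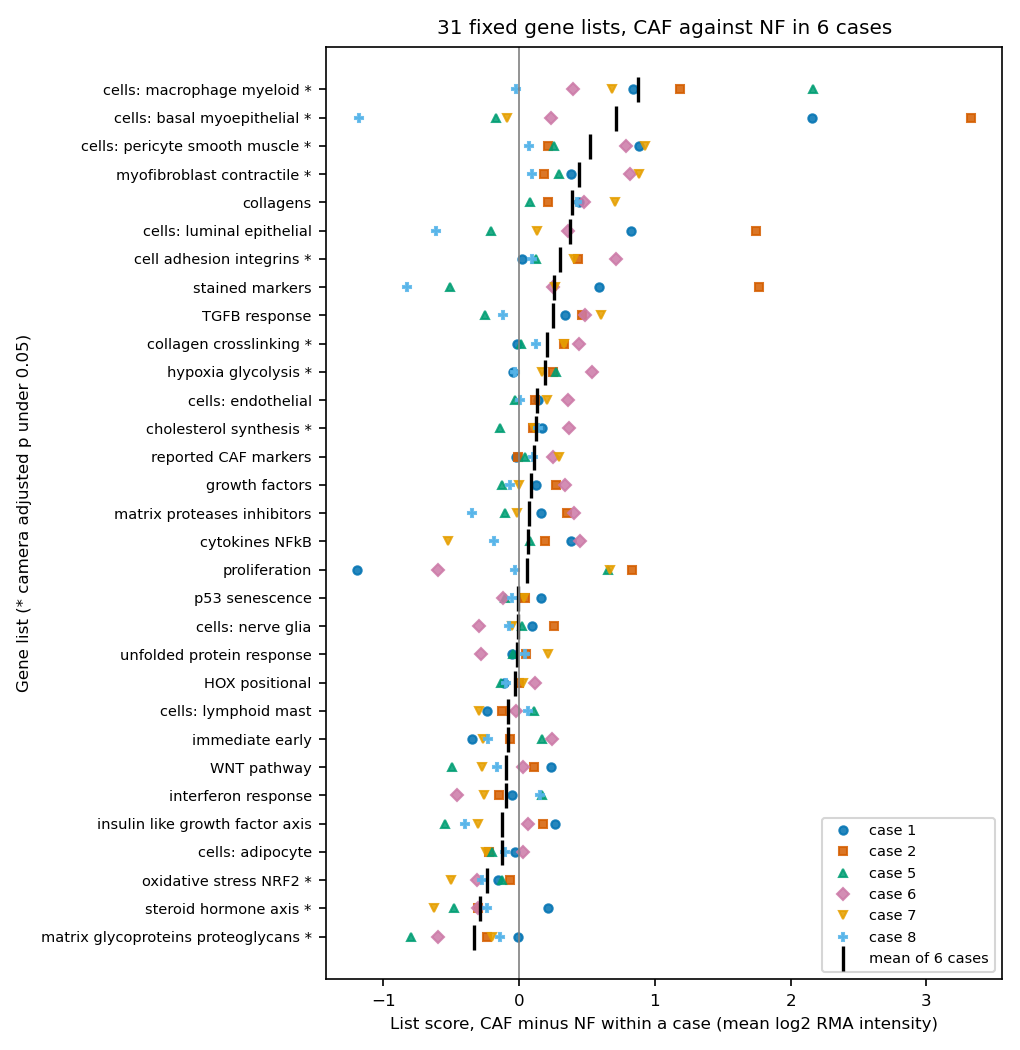
List score (mean log2 RMA intensity of the members) of CAF minus that of NF within each case (horizontal axis) for the 31 fixed gene lists (vertical axis), with a point per case, and the mean of 6 cases as a black bar. Asterisks mark the 11 lists called by camera with its preset correlation, and the basal list spreads most, from -1.18 in case 8 to 3.33 in case 2.

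In all, camera called 11 of the 31 lists, 8 higher and 3 lower in CAF. With an estimated correlation 0 lists were called, fry called 0, and sign flips of the list scores called 0, with 6 lists on 1 side in all 6 cases at the smallest exact p that 64 flips allow (0.03125). The 31 other assignments of CAF and NF within cases gave from 3 to 15 called lists, so chance is not excluded for the number of lists.

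Markers of macrophages and of basal epithelial cells were higher in some CAF cultures than in their NF. Of 17 macrophage and myeloid genes, none of them above the median of all kept probe sets in NF, 13 rose and 0 fell when adjusted over the list alone, and 0 passed over all probe sets. The integrin chain ITGB2 rose by 1.23 (SE 0.21), LAPTM5 by 1.64 (SE 0.34), the Fc receptor subunit FCER1G by 1.25 (SE 0.27) and CD74, which guides antigen loading, by 1.29 (SE 0.30). The list averaged 0.87 in 5 of 6 cases (camera, adjusted p = 1.46e-06, and adjusted p = 0.786 with an estimated correlation), from -0.03 in case 8 to 2.17 in case 5, and scores were highest in CAF 2 (7.80) and CAF 5 (7.62).

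Basal and myoepithelial genes averaged 0.71 (camera, adjusted p = 0.00683, and adjusted p = 0.823 with an estimated correlation), but only 3 of 6 cases were higher and 0 of 15 genes passed by either adjustment. Case 1 differed by 2.16 and case 2 by 3.33, with KRT15 and S100A2 at a mean of 1.17 (SE 0.60) and 0.83 (SE 0.40), whereas case 8 differed by -1.18. The call ended without case 1 (0.43, adjusted p = 0.112) or case 2 (0.18, adjusted p = 0.374), without both the mean was -0.31 (adjusted p = 0.248), and without case 8 it was 1.09. The oxytocin receptor gene OXTR, also a basal marker, was bright in both cultures and stood at 0.34 (SE 0.09). Luminal epithelial markers, 5 of them in other lists, averaged 0.37 in 4 of 6 cases and missed the threshold (camera, adjusted p = 0.0835), while passing without the case as a block (0.0297), without the filter (0.0323) and without case 5 (0.0245), 7 (0.0393) or 8 (0.0086). Much of the mean came from case 2, which differed by 1.74, as it fell to 0.09 without case 2 (adjusted p = 0.736), to 0.27 without case 1 (0.292) and to -0.07 without both (0.747). GATA3, a luminal transcription factor, alone of 20 rose when adjusted over the list alone, by 1.86 (SE 0.39, 5 of 6 cases), and 0 over all probe sets, with SPINT2 at 0.99 (SE 0.28).

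**Figure D3:**
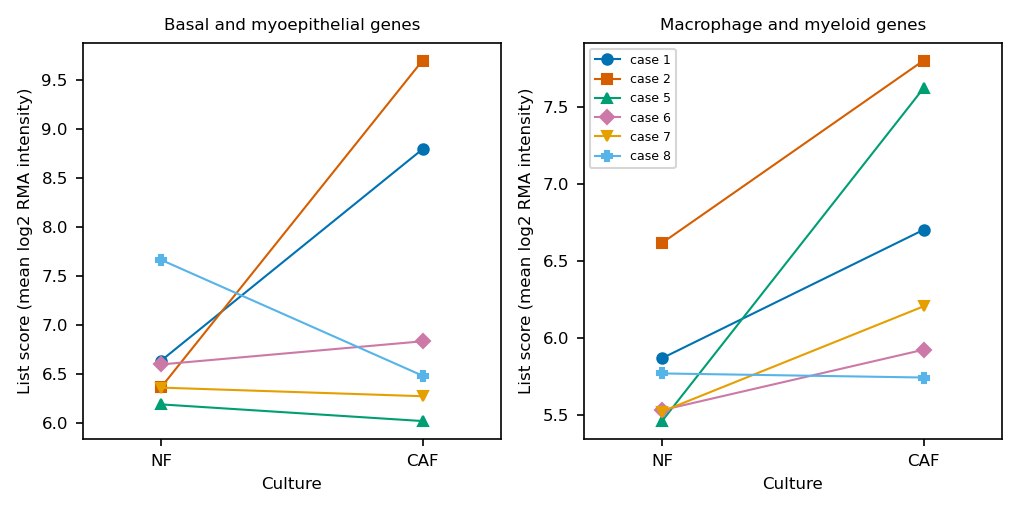
List scores (mean log2 RMA intensity, vertical axis) of basal and myoepithelial genes (left) and of macrophage and myeloid genes (right) in NF and CAF cultures (horizontal axis), with a line per case. The basal score reaches 8.79 in CAF 1 and 9.69 in CAF 2, and the myeloid score 7.80 in CAF 2 and 7.62 in CAF 5.

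Markers of the remaining cell types gave little. Of 14 endothelial genes, none above the median of kept probe sets in NF, ERG, an endothelial transcription factor, alone rose when adjusted over the list alone, by 1.49 (SE 0.22, 6 of 6 cases), and 0 over all probe sets, while the list averaged 0.13 in 5 of 6 cases (camera, adjusted p = 0.391). The sialomucin EMCN stood at -0.98 (SE 0.29). Lymphocyte and mast cell markers averaged -0.08 with 2 of 6 cases higher (camera, adjusted p = 0.599), and KIT stood at -0.58 (SE 0.15). Adipocyte markers had a mean of -0.13 and a median of 0.05, with 1 of 6 cases higher and a test pointing down (camera, adjusted p = 0.956), and the fatty acid transporter CD36 at -1.39 (SE 0.47). For the 4 measured Schwann cell markers, among them ERBB3 at -0.15 (SE 0.29), the mean of -0.01 differed in sign from the median of 0.02 and from the test (camera, adjusted p = 0.921, 3 of 6 cases higher). In these last 3 lists, 0 of 9, 0 of 15 and 0 of 4 genes passed by either adjustment.

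Most of the variation lay between cases. Their share over kept probe sets was 59.1%, where the degrees of freedom alone give 45.5%, that of CAF against NF was 15.5% against 9.09%, and 25.3% was left. A donor effect shared by both cultures of a case passed for 1020 probe sets, 3.11% of those tested (limma moderated F, adjusted p under 0.05), and 7093 had an unadjusted p under 0.05. The largest F belonged to the interferon-inducible GTPase gene GBP3 (291), LOC402110 (225), the angiotensinogen gene AGT (187), ACAT2, which makes acetoacetyl-CoA (119), CYB5B (118), SUSD2 (108), ARRDC3 (104) and MGC9913 (103). The count fell to 69 without case 2, 229 without case 6, 240 without case 7 and 432 without case 8.

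**Figure D4:**
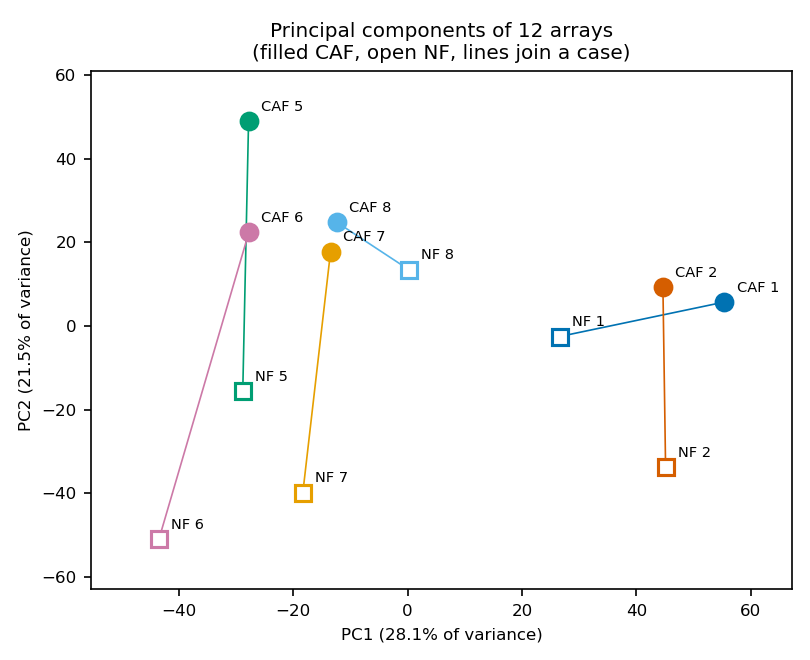
Scores of the 12 arrays on the first principal component (horizontal axis, 28.1% of the variance) and the next (vertical axis, 21.5%), with filled CAF and open NF symbols and lines that join the cultures of a case. Both cultures of cases 1 and 2 lie at 26.6 or above on the first component and all other arrays at 0.216 or below, and in every case the CAF array lies above its NF array on the next.

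No difference in heterogeneity between CAF and NF cultures was detected. The mean distance between arrays was 0.464 log2 units among CAF and 0.490 among NF, a difference of -0.026 that was no larger than swaps within cases gave (exact permutation, two-sided p = 0.5625 over 64 assignments, smallest possible 0.03125). Over the 1000 most variable probe sets the difference was 0.073 in the other direction (exact permutation p = 1). The SD was larger in CAF for 42.7% of probe sets, with a median of 0.177 in CAF and 0.197 in NF. Limma on absolute deviations called 0 probe sets, with a lowest adjusted p of 0.156 and 1487 at an unadjusted p under 0.05, 489 more variable in CAF and 998 in NF. Genes with the smallest p were NPTX1, CCR1, IGF2, PPP1R14C and CD14 on the side of CAF, with the neuronal pentraxin NPTX1 at an SD of 1.33 in CAF against 0.46 in NF and the monocyte receptor CD14, a member of the myeloid list, at 1.49 against 0.72. On the side of NF were SKIC3, KLF6, SEMA3C, ROR2 and ADAM10, with the semaphorin SEMA3C at 0.19 in CAF against 0.90 in NF and the metalloprotease ADAM10 at 0.13 against 0.57. The authors' deposited table has 5 probe sets with a q under 0.05 in its variance test, 2 with the larger variance in CAF and 3 in NF.

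The change from NF to CAF was partly shared between cases. The profiles of differences correlated with a mean of 0.251 over the 15 pairs of cases, from -0.006 for cases 1 and 5 to 0.561 for cases 6 and 7, across probe sets, which are not independent replicates. That mean was the highest of the 32 assignments of CAF and NF within cases (exact permutation, one-sided p = 0.03125, the smallest possible), and the next was 0.170. With 5 cases the smallest possible p is 0.0625, which each case left out gave, at means from 0.190 to 0.318. The size of the change varied, since 416 probe sets differed at least 2-fold in case 8, 819 in case 2, 1117 in case 7, 1280 in case 1, 1612 in case 6 and 1857 in case 5. The root mean square difference between CAF and NF ran from 0.277 in case 8 to 0.522 in case 5.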

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

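The tests of epithelial and macrophage RNA and of GATA3, TFAP2A and TFAP2C in this part were chosen only after the list results were seen. Single arrays far from the other 5 of their group were looked for in the named genes and the lists by the gap to the nearest array. Chance alone marks about 1 in 20 groups, or 5%, and 12 of 310 gene groups and 2 of 62 list groups were marked. NF 2 holds 6 of these 14 values.

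NF 2 had the highest log2 intensity of the NF for COL10A1 (8.36), the myeloid genes FCER1G (7.74) and CD14 (7.74), the chemokine receptor CCR1 (6.54) and the p53 target TP53INP1 (11.07), and the highest myeloid list score (6.62). NF 8 was highest for LEF1 (6.88) and for the basal list score (7.66), and NF 6 lowest for INHBA (9.72). Among CAF, CAF 5 was lowest for PRR15 (6.15), CAF 6 lowest for BHLHE40 (9.79) and ROR2 (6.79), and CAF 2 highest for CIDEA (6.01) and the mast cell gene TPSAB1 (7.13).

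Basal and myoepithelial genes stood far above the other cultures in CAF 1 and CAF 2 and, by less, in NF 8. Differences of single members between CAF and NF correlated with a mean of 0.79 over the 6 cases, but cell cycle genes reached 0.722. Without case 2 the basal value fell below theirs (0.718 against 0.735). This correlation therefore cannot tell RNA of residual epithelial cells apart from genes that change together in the fibroblasts of cases 1 and 2. Of the luminal list, EPCAM and CDH1 differed by 2.42 and 2.77 in case 1 and by 4.03 and 3.77 in case 2. In case 8 they stood at -1.12 and -1.32, as the basal genes were lower there too. KRT18 (0.44 and 0.14) and CLDN4 (-0.30 and -0.19) showed no such rise in cases 1 and 2, so the question stays open. KRT14 differed by 6.26 in case 2 and by -2.74 in case 8, although per the protocol the RNA was taken once epithelial cells had disappeared, and 4 of the 15 genes lay above the median of kept probe sets in NF. A change of the fibroblasts in every CAF culture is argued against, since only 2 of 6 cases exceeded 0.5 and cases 5 to 8 averaged -0.30. For GATA3, TFAP2A and TFAP2C, transcription factors at 1.86, 1.74 and 1.48 with adjusted p of 0.128, 0.0765 and 0.0973, the median of the 3 was 2.485, 0.61 and 0.69 in cases 5, 7 and 8, where the basal list was not higher in CAF, but GATA3 stood at -0.17 in case 8, so epithelial RNA and a change of the fibroblasts cannot be told apart for them.

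Myeloid genes were highest in CAF 5 and CAF 2, with NF 2 the highest of the NF. Differences of the 17 members correlated with a mean of 0.51 over the 6 cases, less than those of cell cycle genes (0.722) and contractile genes (0.526), so this value does not point to RNA of residual macrophages rather than genes that change together in fibroblasts. Lysozyme, LYZ, an abundant macrophage transcript that the filter on dim probe sets left out, was 3.05 higher in CAF 5 and 2.33 higher in CAF 2. CD163 (3.50 and 1.18), CD14 (3.52 and 1.49) and PTPRC (1.17 and 1.18) rose in the same cultures. The macrophage marker CD68 did not (0.00 and -0.28), and MSR1 hardly did (0.24 and 0.23). PTPRC and MSR1 were also left out by the filter. The list was not higher in CAF of case 8 (-0.03), so the rise was not shared by every CAF culture. For the cultures where the list rose, with 4 of 6 cases above 0.5, RNA of macrophages and a change of the fibroblasts cannot be told apart. The staining named in the labels covered epithelial, endothelial and mesenchymal markers, and a macrophage stain is not given in the sources used here.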

How the results depend on the processing

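Fits without cases 1 and 2, without cases 2 and 5 and with list scores as covariates were chosen after seeing the data. The 13 calls of CAF against NF became 5 without the case as a block and 117 with the case as a random block, of which 4 and 9 were among the 13. Array weights gave 93 calls, with all 13 among them, 1 probe set per gene gave 7, an adjusted p under 0.1 gave 231, and an unpaired empirical Bayes mixture gave 107, of which 55 were at least 2-fold. Leaving out 1 case gave from 0 (without case 2, 6 or 7) to 49 calls (without case 1). Without cases 1 and 2 there were 24, without cases 2 and 5 there were 0 (3374 at an unadjusted p under 0.05), with the myeloid score as covariate 0 (2203), and with the basal score 2. Filter, variance prior, centring and repeated quantile normalization gave 13 to 17 calls, and values from the workbook changed nothing as they are identical. Fewer cases and added covariates cost precision, and otherwise the cause was not tested. On lines over the myeloid score, the 12 called genes had a median change of 1.22 where that score did not differ. Over the basal score this median was 1.17, against 1.23 over all cases. These genes were called because they changed in every case, which favours such medians. The myeloid score was not higher in CAF in only 1 case, so the medians do not show that the calls hold.

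Of 11 called lists, 0 were called by camera with an estimated correlation and 0 by fry. With 1 case left out camera called 9 to 14 lists, 8 to 11 of them among the 11. Without the block the pairing changed 3 list calls, with adjusted p of 0.228 for sterol synthesis, 0.0297 for collagens and 0.0297 for luminal genes, and no other list call. The basal list turned to -0.31 without cases 1 and 2. Donor effects ranged from 69 (without case 2) to 828 (without case 5), with 229, 240 and 432 without case 6, 7 or 8. The shared profile ranged from 0.190 (without case 7) to 0.318 (without case 1), where 5 cases allow no smaller p than 0.0625. The difference in distance turned to 0.073 over the 1000 most variable probe sets, and the tests of spread, pairing and list scores kept their side of the threshold.

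For the 145 genes of the naming rule, 1591 of 1748 values under alternatives kept direction and side of the threshold, 90 lost a call, 20 gained one, 0 called values reversed, and 47 values of 26 genes had the other sign without a call. Most of these genes had no call to lose, and for the 12 called in CAF against NF only 50 of 108 values stayed past the threshold over 9 fits (1 case left out, no block, no filter, centred arrays). Of 155 other probe sets, 135 had the sign of the named one. Probe sets near the lowest kept mean intensity of 33.1 carry mostly background, so small folds of dim genes such as FAM110B are compressed.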

Other observations

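The tests of the 12 genes against list scores and the genes outside the naming rule in this part were chosen only after the results were seen, as was the count at an unadjusted p without the block, and the other tests against other assignments were planned.

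Outside the fixed lists, and chosen after their values were seen, a few genes had wider differences than the 12 called. ST6GALNAC5, which adds sialic acid to gangliosides, stood at 3.47 (SE 0.51) and 2.40 (SE 0.40) by its probe sets, higher in 6 of 6 cases, with adjusted p of 0.0693 and 0.0823 in limma. SLC24A3, a potassium-dependent sodium and calcium exchanger, stood at 2.76 (SE 0.42) and 2.29 (SE 0.35) in 6 of 6 cases, with adjusted p of 0.0699 and 0.0716. GALNT3, which starts O-linked glycosylation, stood at 2.38 (SE 0.44) in 5 of 6 cases (limma, adjusted p = 0.102).

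How well 5 cases foretold the left-out one was also measured. Of the 100 probe sets with the smallest p among the other 5 cases, 98 pointed the same way in case 7, 92 in case 6, 89 in case 2, 79 in case 5, 72 in case 8 and 66 in case 1. The slope of the left-out differences on the mean of the others was 1.35 in case 7, 1.13 in case 6, 0.71 in case 5, 0.59 in case 2, and 0.21 in both case 1 and case 8.

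Chance was examined by swapping CAF and NF within cases, which parts all 6 pairs in each of 32 assignments. The real assignment gave the most calls, 13 against 6 in the highest other. It also gave the most probe sets at an unadjusted p under 0.05, 5025 against 3942 in the highest other. A share of 1 of 32 is the smallest these swaps allow, which makes chance less likely for both counts but does not exclude it. The 11 called lists did not stand out, since 6 of 32 assignments gave as many and the highest other gave 15. Nor did the 1487 probe sets of the spread test at an unadjusted p under 0.05, since 3 of 32 gave as many and the highest other gave 1762. Without the block, 1 of 100 drawn from 462 splits of the 12 arrays gave 5 calls, the real one, and the highest other gave 1. Only 8 of the other splits part all 6 pairs as the real one does, too few to exclude chance for the 5 calls. Chance was not excluded either for the 3228 probe sets at an unadjusted p under 0.05 without the block. There, 7 of 100 splits gave as many and the highest other gave 4554. Of the 6 other splits among these, 5 part 2 of the 6 pairs and 1 parts 4, and the 8 others that part all 6 pairs gave at most 2436.

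One hypothesis was that RNA of macrophages or epithelial cells underlies the 12 called genes. The basal list was not higher in CAF in cases 5, 7 and 8 (-0.17, -0.09 and -1.18). The median change of the 12 genes in the called direction was 1.10, 1.33 and 0.96 there (lowest gene 0.53). These genes were called because they changed in every case, so these values cannot decide on RNA of basal epithelial cells as the cause. The myeloid list was not higher in case 8 alone (-0.03), with a median change of 0.96, and 1 case is too few, so RNA of macrophages and a difference of the fibroblasts between CAF and NF cannot be told apart for these genes. With the myeloid score as covariate 0 of the 13 calls were left and with the basal score 1, beside 1 new call. The changes themselves stayed about as large on lines of each gene's case differences over a score, which the choice of these genes favours. Where the myeloid score did not differ, the median of the 12 genes was 1.22 (lowest 0.60), against 1.23 over all cases. For the basal score it was 1.17 (lowest 0.69). For RASGRF2 the myeloid line gave 2.36 against 2.26 before, and for TNFSF4 1.95 against 2.36. The SE of RASGRF2 was 0.35 on that line, without moderation, and 0.17 in the moderated fit, so these 2 are unlike measures.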
